A study of Arabidopsis thaliana with 18 samples.

How the data were processed

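RNA was measured in roots of 5-day-old Arabidopsis thaliana seedlings grown on half-strength Murashige and Skoog medium. The 18 libraries fell into 6 groups of 3. In 5 groups a GAL4 driver line (J0951, J0571, Q2500, J0121 or Q0990) carried UAS-YUC4, a transgene that places YUC4, a flavin monooxygenase of auxin synthesis, under the control of GAL4. The remaining group, J0951/Col, held the J0951 driver without UAS-YUC4 and served as the control. The labels do not say in which root cells each driver is active. Only J0951/UAS-YUC4 shared its driver with the control. In the other 4 comparisons the driver line and the transgene changed together, so none of their differences can be assigned to YUC4 alone.

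Per the labels' protocols, roots were frozen in liquid nitrogen, total RNA was extracted with a TIANGEN kit, complementary DNA was made with random primers and libraries were sequenced on an Illumina HiSeq instrument. The authors deposited a table of FPKM values, which are fragments scaled by transcript length and library size, for 25202 loci, rounded to 2 decimals. The aligner and the genome build are not given in the sources used here. The table holds 18 columns of values, and 0 of them were left out. Read counts and the number of reads per library are not in the table, so the depth per library is unknown, no counting interval can be given, and a value of 0 has no stated upper limit. How many plants or pools the 3 libraries of a group came from is likewise not given in the sources used here. The p-values measure only the spread between libraries, which may be technical.

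Values were transformed to log2(FPKM + 1). A fold change is therefore a difference on this scale, and it understates the change of genes with low FPKM. Of the 25202 loci, 98 were at 0 in every library. Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 19260. A linear model with 1 mean per group was fitted to all 18 libraries in limma 3.58.1 under R 4.3.3, with variances moderated along a mean trend. The residual degrees of freedom were 12, and the median standard error of a comparison was 0.099 on the log2 scale. Each UAS-YUC4 group was compared with J0951/Col, each was compared with the mean of the other 4 UAS-YUC4 groups, and the 5 were compared together by an F test. P-values were adjusted within each comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Changes are given as log2 fold changes with the mean and standard deviation (SD) of FPKM, and n = 3 libraries per group throughout unless another n is stated.

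Gene names and the order of neighbouring genes came from a RefSeq annotation of the TAIR10.1 assembly, which was not used to place the values. It matched 25000 nuclear loci, of which 9647 carried a symbol, and the table also held 87 plastid-encoded and 115 mitochondrial genes. Reads were not assigned anew, so values of near-identical copies such as AT5G46890 and AT5G46900, or of members of the RBCS and LHCB families, are uncertain as to which copy they came from. The strand of the reads is likewise unknown, so genes that overlap on opposite strands cannot be told apart.

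Gene lists were tested with camera in limma, at a preset inter-gene correlation of 0.01, with the Benjamini-Hochberg adjustment over the 28 lists of a comparison. The lists held 475 entries, and the annotation gave 446 of the symbols, while 29 were kept by their written locus. They covered Aux/IAA repressors, auxin conjugation and oxidation, SAUR genes, auxin biosynthesis, auxin transport, auxin receptors with ARF transcription factors, lateral root initiation, root meristem, cell cycle, root hairs, the Casparian strip, suberin, xylem secondary wall, and vascular patterning with phloem. They further covered cytokinin, ethylene, iron deficiency, phosphate starvation, nitrate response, flavonoids, aliphatic glucosinolates, jasmonate with wounding, salicylate with defence, abscisic acid with water stress, shoot photosynthesis, epidermis with lateral root cap, cortex with endodermis, and pericycle with stele. The test compares the mean test statistic of the genes of a list with that of all other tested genes. Its result can differ in sign from the median and the mean of the list. List tests were repeated with a correlation estimated for each list and with fry. Counts of list members are given over all genes tested, and also adjusted over the list alone where these differ.

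The groups, the tests of the comparisons, the gene lists, the alternatives and the rule for which genes are named were made before the data were examined, apart from the tests and choices said below to have been made after the results were seen. The rule took YUC4, a panel of 12 auxin response and root genes whatever their result, the 8 highest and 8 lowest changes among called genes whose libraries did not overlap and whose higher mean was at least 5 FPKM, and up to 4 members of each called list with the smallest adjusted p. The result of 1 gene of the panel is not reported here. For genes that set 1 line apart it took the 4 highest and 4 lowest, and for genes changed in all 5 lines up to 6 in each direction. ACS4, a member of the panel, was listed at 0 FPKM in every library and could not be tested.

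Alternatives were a pseudocount of 0.1, no filter on low values, a minimum of 5 FPKM in 3 libraries, median-of-ratios scaling, quantile normalization, weights per library, replicate numbers as a block, a fit of the 2 groups compared alone, and fits with 1 library left out. Fits without the Q0990/UAS-YUC4 group were added after the data were seen. The model was tested on simulated values. In the J0951 comparison it recovered 59.7%, 95.5% and 100% of genes shifted by 0.5, 1 and 2 on the log2 scale. False calls were 9 among 18793 genes. Shifts of 0.5 were recovered at 74.6%, 65.7%, 73.1% and 65.7% in the J0571, Q2500, J0121 and Q0990 comparisons. Replicates differed most in Q2500/UAS-YUC4 (log2 SD up to 0.352, elsewhere 0.254), so recovery there may be lower. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.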

Results

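Transcript levels were measured in roots of Arabidopsis seedlings in 18 libraries, 3 for each of 6 genotypes. In 5 genotypes a GAL4 driver line carried UAS-YUC4, and in the control, J0951/Col, the J0951 driver was present without it. Summed FPKM per library ranged from 650929 to 678093, and between 18321 and 18724 genes per library reached 1 FPKM. The number of reads per library is not given in the sources used here. The first 3 principal components held 41.8%, 17% and 10.3% of the variance. Within groups the lowest correlation between libraries was 0.981, in Q2500/UAS-YUC4, and replicate 3 of that group correlated most closely with replicate 2 of J0121/UAS-YUC4 (r = 0.994). The 10 most abundant genes took between 5.57% and 5.98% of summed FPKM in the control libraries and between 3.58% and 3.86% in the J0951/UAS-YUC4 libraries. All changes below are differences of log2(FPKM + 1), and FPKM levels are means ± SD with n = 3 libraries.

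The first question was whether the transgene was expressed in each line. YUC4 (AT5G11320), which encodes a flavin monooxygenase that makes auxin, stood at 0.24 ± 0.0794 FPKM (SD, n = 3) in the control. It rose to 37.6 ± 6.6 FPKM in J0951/UAS-YUC4, which was 156 times the control mean, and to 74.1 ± 5.51 FPKM in J0571/UAS-YUC4, which was 309 times. In Q2500/UAS-YUC4 it reached 102 ± 15.7 FPKM, 424 times the control mean, and in J0121/UAS-YUC4 825 ± 88.2 FPKM, 3439 times. The limma adjusted p was at most 2.1e-06 in these 4 lines. The libraries labelled Q0990/UAS-YUC4 held 1.68, 11.95 and 0.29 FPKM, so replicate 3 lay inside the control range of 0.15 to 0.30 FPKM. The log2 fold change there was 1.52 with a standard error of 0.49 and was not called (adjusted p = 0.12), while without replicate 3 of that group the adjusted p was 0.037. An exact permutation test of 3 against 3 libraries cannot go under 0.1, and it gave p = 0.1 in the other 4 lines and p = 0.2 in Q0990/UAS-YUC4. A mean over 6 auxin response genes stood at 1.99 ± 0.05 on the log2 scale in the control. It was 3.48 ± 0.11 in J0951/UAS-YUC4, 2.77 ± 0.14 in J0571/UAS-YUC4, 2.73 ± 0.14 in Q2500/UAS-YUC4, 2.90 ± 0.01 in J0121/UAS-YUC4 and 1.92 ± 0.08 in Q0990/UAS-YUC4.

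**Figure D1:**
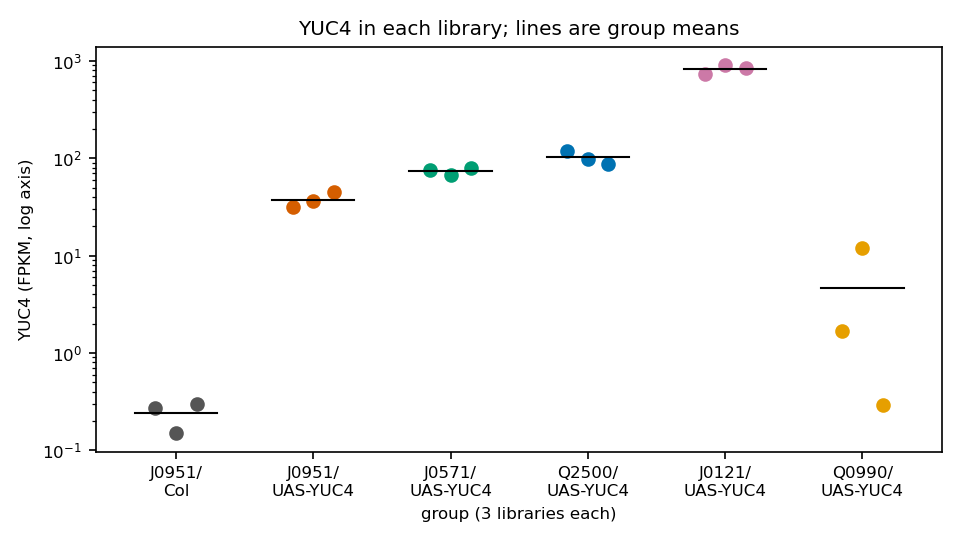
YUC4 level (FPKM, log axis) in each of the 18 libraries, grouped by genotype, with a line at each group mean. Means ran from 0.24 FPKM in J0951/Col to 825 FPKM in J0121/UAS-YUC4, and the libraries labelled Q0990/UAS-YUC4 spread from 0.29 to 11.95 FPKM.

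The comparison of J0951/UAS-YUC4 with J0951/Col asked what changed in roots when YUC4 was added to a line with the same driver. GH3.3 (AT2G23170), an enzyme that conjugates auxin to amino acids, rose by 2.61 on the log2 scale, from 2.71 ± 0.248 to 21.8 ± 3.15 FPKM. IAA5 (AT1G15580) and IAA19 (AT3G15540), repressors of the auxin response, rose by 1.99 and 1.47, to 4.22 ± 0.322 and 23.8 ± 2.78 FPKM from 0.323 ± 0.237 and 7.97 ± 1.26 FPKM. Lower levels were called in 14 of 16 suberin, 12 of 13 xylem secondary wall and 7 of 12 Casparian strip genes, and each of these lists had an adjusted p = 0.21 with an estimated correlation.

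Among the panel genes, GH3.5 (AT4G27260) rose by 1.36 to 44.8 ± 3.42 FPKM, IAA29 (AT4G32280) by 0.82 to 1.55 ± 0.364 FPKM and GH3.1 (AT2G14960) by 0.67 to 4.84 ± 1.05 FPKM, with adjusted p at most 0.00099. RSL4 (AT1G27740), a transcription factor of root hair growth, rose by 0.46 to 12.7 ± 0.455 FPKM (adjusted p = 0.014). LBD16 (AT2G42430), a transcription factor of lateral root initiation, rose by 0.32 to 6.54 ± 0.207 FPKM (adjusted p = 0.016). LBD29 (AT3G58190), of the same family as LBD16, fell by 0.37 on the log2 scale to 1.68 ± 0.327 FPKM (adjusted p = 0.026). These last 2 calls each depended on single libraries. That of LBD16 ended without J0951/Col replicate 3 (adjusted p = 0.084). That of LBD29 ended without J0951/Col replicate 1 (adjusted p = 0.085), J0951/Col replicate 2 (adjusted p = 0.098) or J0951/UAS-YUC4 replicate 3 (adjusted p = 0.14), and in a fit of the 2 groups alone (adjusted p = 0.057). LBD18 (AT2G45420) stood at 2.15 ± 0.150 FPKM against 2.24 ± 0.205 FPKM and was not called (adjusted p = 0.81).

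After YUC4 the largest increase was in ASN1 (AT3G47340), an asparagine synthetase, which rose by 4.16 from 0.473 ± 0.0851 to 25.8 ± 5.84 FPKM. MLP28 (AT1G70830), a major latex protein gene, rose by 3.73 to 16.8 ± 3.55 FPKM, and RBCS3B (AT5G38410), a small subunit gene of Rubisco, by 3.61 to 16.6 ± 4.68 FPKM. SAUR76 (AT5G20820), a small auxin up RNA, rose by 3.36 to 26.0 ± 1.19 FPKM, and AT3G28320 by 3.29 to 21.9 ± 2.10 FPKM. ACS9 (AT3G49700), an enzyme of ethylene synthesis, rose by 3.22 from 0.0767 ± 0.0404 to 9.06 ± 1.21 FPKM, and ZFP2 (AT5G57520), a zinc finger gene, by 3.16 to 8.85 ± 1.93 FPKM. The lowest change was in AT1G21313, which fell by 3.49 on the log2 scale from 699 ± 127 FPKM to 110 FPKM, although its SD of 141 FPKM there exceeded its mean. AT5G64120, a peroxidase gene, fell by 3.23 from 560 ± 81.6 to 58.4 ± 2.29 FPKM, and TIP2;3 (AT5G47450), an aquaporin of the vacuolar membrane, fell by 2.75 from 242 ± 29.4 to 35.1 ± 1.92 FPKM. AT1G05650 fell by 2.90 to 0.840 ± 0.135 FPKM and AT3G05900 by 2.84 to 5.44 ± 3.57 FPKM. The plastid ribosomal protein genes ATCG00780, ATCG00790 and ATCG00810 fell by 3.15, 2.87 and 2.78. The adjusted p was at most 9e-04 for all of these genes.

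Of 16 tested suberin genes 14 fell (camera adjusted p = 1.1e-07, and adjusted p = 0.21 with an estimated correlation). They included GPAT5 (AT3G11430), an acyltransferase of suberin monomer synthesis, which fell by 0.97 from 20.7 ± 1.96 to 10 ± 0.835 FPKM, and ABCG2 (AT2G37360), a transporter of the suberin barrier, which fell by 0.86 to 11.6 ± 1.07 FPKM. Xylem secondary wall genes fell in 12 of 13 cases (adjusted p = 1.1e-07, and adjusted p = 0.21 with an estimated correlation), among them LAC17 (AT5G60020), a laccase of lignin formation, by 0.77 to 18.7 ± 1.92 FPKM, and XCP2 (AT1G20850), a xylem protease, by 0.79 to 60.0 ± 7.05 FPKM. In the Casparian strip list 7 of 12 genes fell (adjusted p = 2e-05, and adjusted p = 0.21 with an estimated correlation), including CASP5 (AT5G15290) by 1.40 to 7.81 ± 0.780 FPKM and CASP4 (AT5G06200) by 0.85 to 14.3 ± 1.01 FPKM. Vascular patterning and phloem genes fell in 7 of 15 cases (adjusted p = 0.0018, and adjusted p = 0.21 with an estimated correlation), including SUC2 (AT1G22710), a phloem sucrose transporter, by 1.01 to 21.6 ± 2.38 FPKM and SEOR1 (AT3G01680), a phloem filament gene, by 0.85 to 11.8 ± 1.42 FPKM. In the pericycle and stele list 5 of 10 genes fell, or 6 adjusted over the list alone, and 1 rose (adjusted p = 0.019, and adjusted p = 0.21 with an estimated correlation).

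Root hair genes rose in 12 of 20 cases (adjusted p = 0.0026, and adjusted p = 0.50 with an estimated correlation), including RHS2 (AT1G12950) by 1.46 to 32.0 ± 2.19 FPKM and RHS19 (AT5G67400) by 1.11 to 137 ± 0.976 FPKM. Epidermis and lateral root cap markers rose in 8 of 11 cases (adjusted p = 0.0076, and adjusted p = 0.21 with an estimated correlation), including the hair patterning genes CPC (AT2G46410) by 0.49 and GL2 (AT1G79840) by 0.47. All 9 tested aliphatic glucosinolate genes rose (adjusted p = 2.5e-05, and adjusted p = 0.23 with an estimated correlation), among them CYP83A1 (AT4G13770) by 2.32 to 42.2 ± 8.03 FPKM and BCAT4 (AT3G19710) by 2.49 to 66.8 ± 15.4 FPKM. Jasmonate and wounding genes rose in 7 of 9 cases, or 8 adjusted over the list alone (adjusted p = 0.0022, and adjusted p = 0.10 with an estimated correlation), including CYP94C1 (AT2G27690), which oxidises jasmonate, by 1.13. In the ethylene list 9 of 15 genes rose and 1 fell (adjusted p = 0.013, and adjusted p = 0.21 with an estimated correlation), and in the salicylate and defence list 6 of 8 rose (adjusted p = 0.013, and adjusted p = 0.21 with an estimated correlation). CYP71A12 (AT2G30750), an enzyme of camalexin synthesis, rose by 2.30 to 4.42 ± 1.03 FPKM.

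Auxin conjugation and oxidation genes rose in 6 of 14 cases and fell in 2 (adjusted p = 0.017, and adjusted p = 0.21 with an estimated correlation), with GH3.2 (AT4G37390) up by 1.88 to 40.1 ± 4.41 FPKM and GH3.6 (AT5G54510) up by 2.04 to 58.5 ± 8.09 FPKM. Of 13 SAUR genes 6 rose and 1 fell, or 3 fell adjusted over the list alone (adjusted p = 0.045, and adjusted p = 0.21 with an estimated correlation), and root meristem genes rose in 8 of 16 cases (adjusted p = 0.033, and adjusted p = 0.52 with an estimated correlation), RGI2 (AT3G24240) by 0.40 and RGI1 (AT5G48940) by 0.44. The Aux/IAA list held 11 genes that rose and 4 that fell, with 13 and 4 adjusted over the list alone, and was not called as a list (adjusted p = 0.074). Markers of shoot tissue moved with this group, since 15 of 16 photosynthesis genes rose (adjusted p = 3.2e-08, and adjusted p = 0.21 with an estimated correlation), LHCB3 (AT5G54270) by 1.83 to 51.2 ± 10.4 FPKM and RCA (AT2G39730) by 1.34 to 43.5 ± 6.55 FPKM. Plastid-encoded genes took between 0.027% and 0.036% of summed FPKM in the J0951/UAS-YUC4 libraries and between 0.043% and 0.068% in the control libraries.

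In all, 7796 of 19260 genes were called in this comparison, 4589 higher and 3207 lower, and 691 of them changed at least 2-fold. The share called higher was 58.9%, and it was 47.5% with median-of-ratios scaling. Camera called 15 of 28 lists, and with an estimated correlation it called 0, with 4 lists at an unadjusted p under 0.05. The 13 lists that were not called had adjusted p between 0.055 and 0.83.

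**Figure D2:**
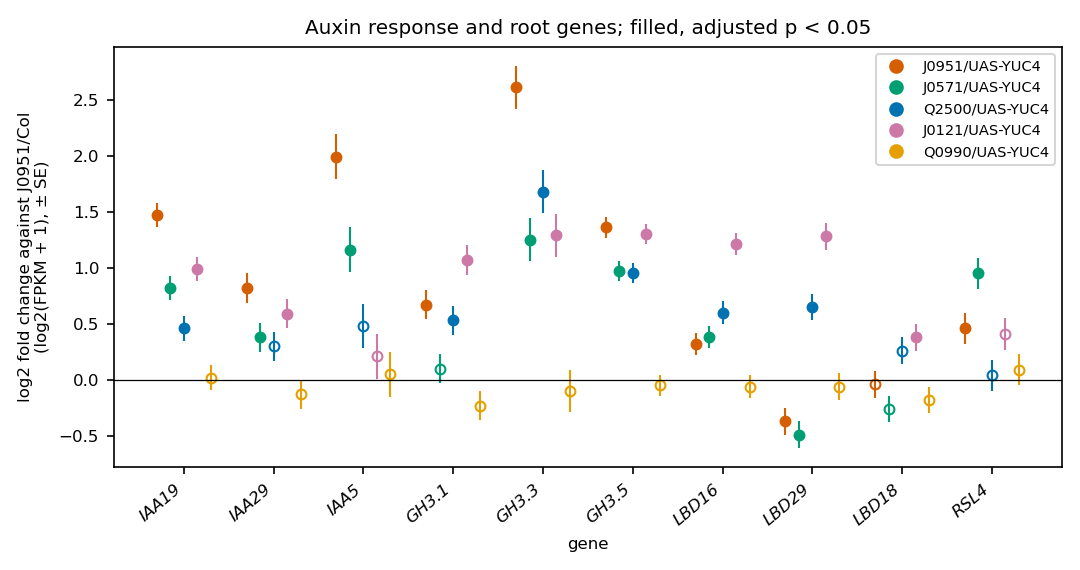
Log2 fold change against J0951/Col (vertical axis, with its standard error) of 10 auxin response and root genes in the 5 UAS-YUC4 lines, with filled marks for an adjusted p under 0.05. GH3.3 reached 2.61 in J0951/UAS-YUC4 and stood at -0.10 in Q0990/UAS-YUC4.

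The comparison of J0571/UAS-YUC4 with J0951/Col asked which genes differed when YUC4 was expressed from a second driver, and driver and transgene changed together in it. GH3.3 rose by 1.25 to 7.96 ± 2.18 FPKM, IAA5 by 1.16 to 2.03 ± 1.03 FPKM and IAA19 by 0.82 to 14.8 ± 1.56 FPKM. In this line 14 of 16 suberin genes fell, and 7 of 12 Casparian strip genes fell while 1 rose, and both lists had an adjusted p = 0.17 with an estimated correlation. RSL4 rose by 0.95, from 8.95 ± 0.414 to 18.5 ± 3.73 FPKM (adjusted p = 0.00011).

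GH3.5 rose by 0.97 to 33.8 ± 2.23 FPKM (adjusted p = 1.4e-06), LBD16 by 0.38 to 6.89 ± 0.726 FPKM (adjusted p = 0.0093) and IAA29 by 0.38 to 0.867 ± 0.0306 FPKM (adjusted p = 0.042). LBD29 fell by 0.49 on the log2 scale to 1.45 ± 0.1 FPKM (adjusted p = 0.0082). The call of LBD16 ended under quantile normalization (adjusted p = 0.05). That of IAA29 ended under median-of-ratios scaling (adjusted p = 0.084) and quantile normalization (adjusted p = 0.20), and without J0951/Col replicate 1 (adjusted p = 0.14) or 2 (adjusted p = 0.10), or J0571/UAS-YUC4 replicate 1 (adjusted p = 0.083), 2 (adjusted p = 0.089) or 3 (adjusted p = 0.095). GH3.1 stood at 2.92 ± 0.578 FPKM (adjusted p = 0.60) and LBD18 at 1.71 ± 0.2 FPKM (adjusted p = 0.11). LBD18 passed the threshold under quantile normalization (adjusted p = 0.038).

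The largest increase was in AT1G64795, which rose by 6 from 0 FPKM in every control library to 63.8 ± 11.4 FPKM. XTH26 (AT4G28850), a wall-modifying xyloglucan enzyme, rose by 3.26 to 25.4 ± 4.68 FPKM, QQS (AT3G30720), a gene that affects starch content, by 3.12 to 45.1 ± 3.28 FPKM and ACS9 by 3.01 to 7.72 ± 1.38 FPKM. EXPA12 (AT3G15370), an expansin, rose by 2.82 to 7.21 ± 0.595 FPKM, AT4G08380 by 2.73 to 5.65 ± 0.770 FPKM and UMAMIT35 (AT1G60050), of a family of amino acid transporters, by 2.69 to 13.5 ± 4.54 FPKM. Among the lowest changes were AT5G46890 and AT5G46900, neighbouring copies of a lipid transfer protein gene, which fell by 3.70 and 3.31 to 33.6 ± 16.2 and 33.4 ± 11.8 FPKM, and whose reads may not be separable. AT5G04120 fell by 3.46 from 21.8 ± 9.03 to 1.14 ± 1.09 FPKM, AT4G12510 by 2.71 to 41.2 ± 7.41 FPKM and AIR1 (AT4G12550), a gene first described as auxin-induced in root cultures, by 2.71 to 52.8 ± 24.1 FPKM. AT1G05650 fell by 2.41 to 1.63 ± 0.640 FPKM, AT4G22460 by 2.26 to 3.02 ± 0.443 FPKM and EXPA17 (AT4G01630), an expansin, by 2.26 to 5.59 ± 2.07 FPKM. The adjusted p was at most 1.2e-05 for all of these genes.

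Suberin genes fell in 14 of 16 cases (camera adjusted p = 5.8e-14, and adjusted p = 0.17 with an estimated correlation), including GPAT5 by 1.06 to 9.42 ± 1.41 FPKM and FAR5 (AT3G44550), a fatty acyl reductase, by 1.08 to 8.62 ± 2.31 FPKM. In the Casparian strip list 7 of 12 genes fell, or 8 adjusted over the list alone, and 1 rose (adjusted p = 5e-07, and adjusted p = 0.17 with an estimated correlation), including CASP1 (AT2G36100) by 1.05 from 207 ± 32.4 to 98.7 ± 6.31 FPKM and ESB1 (AT2G28670) by 0.99 to 65.9 ± 6.72 FPKM. Of 13 xylem secondary wall genes 7 fell, or 9 adjusted over the list alone (adjusted p = 1.2e-07, and adjusted p = 0.17 with an estimated correlation), including FLA11 (AT5G03170) by 0.89 to 15.9 ± 1.84 FPKM. Vascular patterning and phloem genes fell in 4 of 15 cases and rose in 1 (adjusted p = 0.031, and adjusted p = 0.42 with an estimated correlation), with SEOR1 down by 0.38 and LOG3 (AT2G37210), which activates cytokinin, up by 0.65.

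Aux/IAA genes rose in 17 of 27 cases and fell in 3, or 18 and 5 adjusted over the list alone (adjusted p = 0.0091, and adjusted p = 0.23 with an estimated correlation), including IAA1 (AT4G14560) by 1.59 from 6.86 ± 0.373 to 22.7 ± 2.17 FPKM. In auxin biosynthesis 9 of 20 genes fell and 3 rose (adjusted p = 0.0013, and adjusted p = 0.17 with an estimated correlation). SUR2 (AT4G31500) and CYP79B3 (AT2G22330), which lie on the indole glucosinolate branch, fell by 0.58 and 0.70, while TAA1 (AT1G70560), the aminotransferase that acts before YUC enzymes, rose by 1.12 to 22.7 ± 3.57 FPKM. Auxin transport genes fell in 8 of 21 cases and rose in 4, or 9 and 5 adjusted over the list alone (adjusted p = 0.0091, and adjusted p = 0.23 with an estimated correlation), with PILS5 (AT2G17500) down by 1.21 to 134 ± 19.6 FPKM and the kinase genes WAG2 (AT3G14370) and PID (AT2G34650) up by 0.86 and 0.69. Phosphate starvation genes fell in 3 of 10 cases and rose in 1, or 5 and 1 adjusted over the list alone (adjusted p = 0.0049, and adjusted p = 0.17 with an estimated correlation), including PHT1;4 (AT2G38940) by 0.57. Cell cycle genes fell in 2 of 22 cases and rose in 1 (adjusted p = 0.045, and adjusted p = 0.51 with an estimated correlation), with CYCB1;4 (AT2G26760) down by 0.35 and CYCA2;3 (AT1G15570) up by 0.46.

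Root hair genes rose in 12 of 20 cases and fell in 1, or 13 and 1 adjusted over the list alone (adjusted p = 0.0034, and adjusted p = 0.51 with an estimated correlation), including RHS19 by 1.5 to 182 ± 26.5 FPKM and COW1 (AT4G34580) by 1.28 to 33.3 ± 5.05 FPKM. In the nitrate list 7 of 14 genes rose and 1 fell, or 12 and 1 adjusted over the list alone (adjusted p = 0.03, and adjusted p = 0.26 with an estimated correlation), with the transcription factor HHO3 (AT1G25550) up by 0.55 and the nitrate transporter NRT1.1 (AT1G12110) down by 0.47. Salicylate and defence genes rose in 5 of 8 cases, or 6 adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.27 with an estimated correlation), including WRKY33 (AT2G38470) by 0.47. Shoot photosynthesis markers moved with this group too, with 14 of 16 genes higher (adjusted p = 1.8e-06, and adjusted p = 0.27 with an estimated correlation), LHCA4 (AT3G47470) by 1.34 to 130 ± 8.84 FPKM and LHCB3 by 1.71 to 46.4 ± 1.45 FPKM.

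The comparison called 5275 genes, 3805 higher and 1470 lower, of which 398 changed at least 2-fold. The share called higher was 72.1%, and 42.1% with median-of-ratios scaling, which moved the median change by -0.102. With that scaling 3058 of the 5275 genes kept their call and direction. Camera called 13 of 28 lists and with an estimated correlation 0, with 6 at an unadjusted p under 0.05, and the 15 lists not called had adjusted p between 0.05 and 0.98.

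The comparison of Q2500/UAS-YUC4 with J0951/Col asked the same of the Q2500 driver, again with driver and transgene changing together. GH3.3 rose by 1.68 to 11.2 ± 3.52 FPKM and GH3.5 by 0.95 to 33.3 ± 2.09 FPKM. LBD16 rose by 0.60 to 8.19 ± 0.622 FPKM and LBD29 by 0.65 to 4.41 ± 0.544 FPKM. Of 13 xylem secondary wall genes 9 fell (adjusted p = 0.17 with an estimated correlation), and of 22 cell cycle genes 10 rose (adjusted p = 0.25 with an estimated correlation).

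The adjusted p was at most 0.0041 for these 4 panel genes. IAA19 rose by 0.46 to 11.4 ± 1.63 FPKM (adjusted p = 0.017) and GH3.1 by 0.53 to 4.24 ± 0.181 FPKM (adjusted p = 0.02). Both of these calls ended with library weights, at adjusted p of 0.068 and 0.15. In a fit of the 2 groups alone IAA19 had an adjusted p of 0.099. The call of IAA19 also ended without J0951/Col replicate 3 (adjusted p = 0.082) or Q2500/UAS-YUC4 replicate 1 (adjusted p = 0.085). That of GH3.1 ended without J0951/Col replicate 2 (adjusted p = 0.053) or 3 (adjusted p = 0.062), or Q2500/UAS-YUC4 replicate 1 (adjusted p = 0.06) or 2 (adjusted p = 0.068). IAA5 stood at 0.840 ± 0.281 FPKM (adjusted p = 0.12), IAA29 at 0.767 ± 0.156 FPKM (adjusted p = 0.15), LBD18 at 2.88 ± 0.280 FPKM (adjusted p = 0.15) and RSL4 at 9.27 ± 0.688 FPKM (adjusted p = 0.87).

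After YUC4, QQS had the largest increase and rose by 2.92 to 39.1 ± 5.76 FPKM. EARLI1 (AT4G12480), of the lipid transfer protein family, rose by 2.77 from 10.2 ± 3.70 to 79.8 ± 39.4 FPKM, and AT5G63250 by 2.71 to 13.3 ± 5.26 FPKM. LTP5 (AT3G51600), a lipid transfer protein gene, rose by 2.38 to 31.2 ± 21.2 FPKM, CDEF1 (AT4G30140), an esterase that degrades cutin, by 2.02 to 39.2 ± 4.88 FPKM, AT5G01870 by 2.01 to 183 ± 59.7 FPKM and GSTF14 (AT1G49860), a glutathione transferase, by 2.00 to 15.9 ± 1.68 FPKM. SWEET11 (AT3G48740), a sucrose transporter, had the lowest change and fell by 2.41 from 43.9 ± 12 to 7.62 ± 3.37 FPKM. SWEET12 (AT5G23660), its close relative, fell by 1.98 to 14.8 ± 14.0 FPKM and SWEET3 (AT5G53190) by 1.79 to 1.42 ± 1.44 FPKM. AT5G04120 fell by 2.11 to 4.09 ± 0.726 FPKM, CYP710A4 (AT2G28860), of a sterol desaturase family, by 2.06 to 1.35 ± 0.641 FPKM and AT2G46765 by 2.01 to 8.66 ± 1.19 FPKM. HIS1-3 (AT2G18050), a linker histone, fell by 1.60 to 46.3 ± 11.8 FPKM and CLE5 (AT2G31083), a signalling peptide gene, by 1.39 to 4.22 ± 1.28 FPKM. The adjusted p was at most 0.008 for these genes. The call of SWEET12 ended in a fit of the 2 groups alone (adjusted p = 0.078) and that of CLE5 with library weights (adjusted p = 0.068).

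Xylem secondary wall genes fell in 9 of 13 cases, or 11 adjusted over the list alone (camera adjusted p = 1.4e-10, and adjusted p = 0.17 with an estimated correlation), including FLA11 by 0.77 to 17.2 ± 1.11 FPKM and LAC17 by 0.66 to 20.3 ± 2.82 FPKM. In the cell cycle list 10 of 22 genes rose, or 18 adjusted over the list alone (adjusted p = 6.1e-07, and adjusted p = 0.25 with an estimated correlation), among them the cyclin genes CYCD3;3 (AT3G50070) by 0.58 to 21.8 ± 1.62 FPKM and CYCB1;2 (AT5G06150) by 0.29 to 19.4 ± 0.671 FPKM, whose calls ended with library weights (adjusted p = 0.055 and 0.082). That of CYCB1;2 also ended in a fit of the 2 groups alone (adjusted p = 0.071). Suberin genes fell in 7 of 16 cases and rose in 1, or 9 and 1 adjusted over the list alone (adjusted p = 5.4e-05, and adjusted p = 0.44 with an estimated correlation), GPAT5 by 0.73 to 12 ± 0.980 FPKM and ABCG20 (AT3G53510) by 0.56 to 14.8 ± 1.94 FPKM, with adjusted p of 0.053 and 0.061 under library weights. In the Casparian strip list 4 of 12 genes fell, or 6 with 1 higher adjusted over the list alone (adjusted p = 0.00029, and adjusted p = 0.43 with an estimated correlation), including CASP1 by 0.61 to 135 ± 14.7 FPKM, with an adjusted p of 0.091 under library weights.

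Aliphatic glucosinolate genes rose in 7 of 9 cases, or 8 adjusted over the list alone (adjusted p = 5.4e-05, and adjusted p = 0.44 with an estimated correlation), including CYP83A1 by 1.27 to 20.6 ± 8.28 FPKM. Root meristem genes rose in 4 of 16 cases and fell in 1, or 8 and 2 adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.61 with an estimated correlation), with RGI2 up by 0.47 to 32.2 ± 0.536 FPKM. Phosphate starvation genes fell in 2 of 10 cases, or 3 adjusted over the list alone (adjusted p = 0.00039, and adjusted p = 0.17 with an estimated correlation), with PAP17 (AT3G17790), an acid phosphatase, down by 0.55 to 6.06 ± 0.0404 FPKM. In the abscisic acid and water stress list 1 of 10 genes fell, or 2 adjusted over the list alone (adjusted p = 0.0025, and adjusted p = 0.42 with an estimated correlation). It was LEA4-5 (AT5G06760), which fell by 0.98 to 0.343 ± 0.300 FPKM (adjusted p = 0.014) and lost its call without J0951/Col replicate 3 (adjusted p = 0.053) and with library weights (adjusted p = 0.17). Shoot photosynthesis markers moved with this group as well, and 8 of 16 rose (adjusted p = 0.00024, and adjusted p = 0.54 with an estimated correlation), LHCB3 by 1.15 to 32.4 ± 9.90 FPKM and LHCA4 by 0.81 to 90.0 ± 9.57 FPKM.

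The comparison called 2180 genes, 1326 higher and 854 lower, of which 140 changed at least 2-fold. The share called higher was 60.8%, with 39% under median-of-ratios scaling and 50.4% in a fit of the 2 groups alone. The count was 400 with library weights and 679 in a fit of the 2 groups alone. It was 1095, 1393 and 1117 without J0951/Col replicates 1, 2 and 3, and 880, 1018 and 3526 without Q2500/UAS-YUC4 replicates 1, 2 and 3. Camera called 9 of 28 lists and with an estimated correlation 0, with 3 at an unadjusted p under 0.05, and the 19 lists not called had adjusted p between 0.12 and 0.91.

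The comparison of J0121/UAS-YUC4 with J0951/Col concerned the line with the highest YUC4 level, and driver and transgene changed together in it too. Of 22 genes of lateral root initiation 13 rose and 2 fell. LBD16 rose by 1.21 from 5.05 ± 0.490 to 13.0 ± 0.649 FPKM, LBD29 by 1.28 from 2.46 ± 0.446 to 7.37 ± 0.878 FPKM and PUCHI (AT5G18560), a transcription factor of early primordia, by 1.38 to 7.18 ± 0.729 FPKM. GH3.5 rose by 1.30 to 42.8 ± 2.43 FPKM and GH3.3 by 1.29 to 8.07 ± 0.950 FPKM.

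GH3.1 rose by 1.07 to 6.66 ± 0.900 FPKM, IAA19 by 0.99 to 16.6 ± 1.00 FPKM and IAA29 by 0.59 to 1.17 ± 0.319 FPKM, with adjusted p at most 0.0093. LBD18 rose by 0.38 to 3.23 ± 0.477 FPKM (adjusted p = 0.039). That call ended with a pseudocount of 0.1 (adjusted p = 0.052), median-of-ratios scaling (adjusted p = 0.083) and quantile normalization (adjusted p = 0.12). It also ended without J0951/Col replicate 1 (adjusted p = 0.065), 2 (adjusted p = 0.12) or 3 (adjusted p = 0.081), or J0121/UAS-YUC4 replicate 2 (adjusted p = 0.11) or 3 (adjusted p = 0.15). IAA5 stood at 0.530 ± 0.305 FPKM (adjusted p = 0.50). RSL4 stood at 12.3 ± 1.86 FPKM (adjusted p = 0.061) and passed the threshold with library weights (adjusted p = 0.017) and in a fit of the 2 groups alone (adjusted p = 0.028).

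QQS rose by 3.18 to 46.8 ± 0.590 FPKM and GSTF14 by 2.25 to 19.9 ± 7.51 FPKM. AGL14 (AT4G11880), a MADS-box transcription factor, rose by 2.08 from 3.24 ± 0.806 to 16.8 ± 2.98 FPKM and AT5G38940, of the germin family, by 2.03 to 25.9 ± 11.9 FPKM. AT2G39980, an acyltransferase gene, rose by 1.85 to 6.16 ± 1.64 FPKM, CDEF1 by 1.79 to 33.1 ± 2.30 FPKM and EARLI1 by 1.70 to 34.6 ± 8.84 FPKM. AT4G33550 had the lowest change and fell by 2.58 from 62.7 ± 6.69 to 9.83 ± 2.58 FPKM. AT5G04120 fell by 2.26 to 3.6 ± 0.894 FPKM, AT3G53980, of the lipid transfer protein family, by 2.09 from 704 ± 67.7 to 169 ± 48.1 FPKM and AT4G14060 by 1.87 to 4.85 ± 1.53 FPKM. AT5G46730, a glycine-rich protein gene, fell by 1.85 to 8.05 ± 0.517 FPKM, LSU1 (AT3G49580), a gene of the sulfur deficiency response, by 1.84 to 2.22 ± 0.741 FPKM, SWEET11 by 1.82 to 12.2 ± 5.92 FPKM and VSP1 (AT5G24780), a jasmonate-responsive storage protein gene, by 1.74 to 8.48 ± 3.97 FPKM. The adjusted p was at most 0.02 for these genes. The call of EARLI1 ended without J0951/Col replicate 3 (adjusted p = 0.054) or J0121/UAS-YUC4 replicate 1 (adjusted p = 0.053), and that of VSP1 without J0951/Col replicate 1 (adjusted p = 0.057) or 3 (adjusted p = 0.071) or J0121/UAS-YUC4 replicate 1 (adjusted p = 0.093).

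In the lateral root initiation list 13 of 22 genes rose and 2 fell, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.00023, and adjusted p = 0.032 with an estimated correlation). CEP5 (AT5G66815), a signalling peptide gene that restrains lateral roots, fell by 1.21 to 1.67 ± 0.387 FPKM. Pericycle and stele markers fell in 3 of 10 cases, or 4 with 1 higher adjusted over the list alone (adjusted p = 0.001, and adjusted p = 0.032 with an estimated correlation). They were HKT1 (AT4G10310), a sodium transporter, by 0.69 to 0.947 ± 0.226 FPKM, CEPD1 (AT1G06830) by 1.24 to 0.560 ± 0.494 FPKM and SUC2 by 0.62 to 28.7 ± 3.78 FPKM, and the call of SUC2 ended without J0121/UAS-YUC4 replicate 1 (adjusted p = 0.051). Aux/IAA genes rose in 14 of 27 cases, or 16 with 2 lower adjusted over the list alone (adjusted p = 0.00011, and adjusted p = 0.094 with an estimated correlation), including IAA26 (AT3G16500) by 0.53 to 33.1 ± 1.08 FPKM and IAA4 (AT5G43700) by 0.45 to 38.8 ± 2.89 FPKM. Auxin biosynthesis genes fell in 3 of 20 cases (adjusted p = 0.00023, and adjusted p = 0.094 with an estimated correlation). They were YUC6 (AT5G25620), a relative of YUC4, by 0.75 to 4.49 ± 0.338 FPKM, CYP79B3 by 0.57 to 108 ± 7.86 FPKM and YUC3 (AT1G04610) by 0.34 to 7.57 ± 0.633 FPKM. The call of CYP79B3 ended without J0951/Col replicate 2 (adjusted p = 0.069) or J0121/UAS-YUC4 replicate 1 (adjusted p = 0.056) or 3 (adjusted p = 0.052), and that of YUC3 ended without any 1 of the 6 libraries, at adjusted p from 0.056 to 0.16.

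Xylem secondary wall genes fell in 7 of 13 cases, or 9 adjusted over the list alone (adjusted p = 4.4e-07, and adjusted p = 0.18 with an estimated correlation), including FLA11 by 0.54 to 20.5 ± 1.66 FPKM. Suberin genes fell in 9 of 16 cases and rose in 1, or 10 and 2 adjusted over the list alone (adjusted p = 5.5e-05, and adjusted p = 0.40 with an estimated correlation), including FAR5 by 0.90 to 9.83 ± 2.62 FPKM and GPAT5 by 0.70 to 12.5 ± 3.15 FPKM. In the abscisic acid and water stress list 4 of 10 genes fell, or 5 adjusted over the list alone (adjusted p = 0.0016, and adjusted p = 0.30 with an estimated correlation), among them P5CS1 (AT2G39800), an enzyme of proline synthesis, by 0.45 to 33.2 ± 1.92 FPKM and LEA4-5 by 1.04 to 0.273 ± 0.165 FPKM. Phosphate starvation genes fell in 2 of 10 cases, or 2 with 1 higher adjusted over the list alone (adjusted p = 0.039, and adjusted p = 0.38 with an estimated correlation). They were PAP17 by 0.46 to 6.56 ± 0.775 FPKM and SPX1 (AT5G20150), a phosphate sensor, by 0.45 to 5.73 ± 0.763 FPKM, and the call of SPX1 ended without J0951/Col replicate 1 or 2 or any J0121/UAS-YUC4 replicate, at adjusted p from 0.062 to 0.17. Root hair genes rose in 6 of 20 cases, or 9 with 1 lower adjusted over the list alone (adjusted p = 0.01, and adjusted p = 0.61 with an estimated correlation), including RHS19 by 1.12 to 140 ± 24.6 FPKM. Aliphatic glucosinolate genes rose in 4 of 9 cases, or 6 adjusted over the list alone (adjusted p = 0.0095, and adjusted p = 0.61 with an estimated correlation), including MAM1 (AT5G23010) by 1.44 to 22 ± 5.03 FPKM.

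The photosynthesis list was called lower in this line (adjusted p = 0.014, and adjusted p = 0.61 with an estimated correlation). Only RBCS1A (AT1G67090) fell, by 0.77 to 47.3 ± 14.8 FPKM (adjusted p = 0.024), and its call ended without J0951/Col replicate 2 (adjusted p = 0.06) or 3 (adjusted p = 0.071) or J0121/UAS-YUC4 replicate 3 (adjusted p = 0.11). The flavonoid list was called lower (adjusted p = 0.019, and adjusted p = 0.61 with an estimated correlation), although limma called 0 of its 9 tested genes and 1 had an unadjusted value under the threshold. With median-of-ratios scaling the phosphate, flavonoid and photosynthesis lists lost their calls, at adjusted p of 0.081, 0.083 and 0.081.

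The comparison called 2557 genes, 1677 higher and 880 lower, of which 132 changed at least 2-fold. The share called higher was 65.6%, and 38.7% with median-of-ratios scaling. With library weights 4409 genes were called. The count was 1170, 1681 and 1681 without J0951/Col replicates 1, 2 and 3, and 1301, 1532 and 1447 without J0121/UAS-YUC4 replicates 1, 2 and 3. Camera called 12 of 28 lists, or 2 with an estimated correlation, and the 16 lists not called had adjusted p between 0.061 and 0.96.

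The comparison of the libraries labelled Q0990/UAS-YUC4 with J0951/Col concerned the line in which YUC4 was not called. The auxin response genes of the panel stood near their control levels. GH3.3 was at 2.48 ± 0.519 FPKM (adjusted p = 0.79), IAA19 at 8.01 ± 0.289 FPKM (adjusted p = 0.95) and GH3.5 at 16.3 ± 2.64 FPKM (adjusted p = 0.79). The largest increases were in AT4G16215, AT1G23915, AT2G19365 and AT1G36085, 4 genes with little or no signal in the control.

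IAA5 stood at 0.357 ± 0.0404 FPKM (adjusted p = 0.91), IAA29 at 0.313 ± 0.134 FPKM (adjusted p = 0.60) and GH3.1 at 2.11 ± 0.412 FPKM (adjusted p = 0.34). LBD16 stood at 4.84 ± 0.828 FPKM (adjusted p = 0.78), LBD29 at 2.31 ± 0.358 FPKM (adjusted p = 0.81), LBD18 at 1.87 ± 0.437 FPKM (adjusted p = 0.39) and RSL4 at 9.73 ± 2.07 FPKM (adjusted p = 0.73).

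AT4G16215 rose by 6.01 from 0.333 ± 0.218 to 85.2 ± 17.0 FPKM and AT1G23915 by 4.48 from 0.293 ± 0.191 to 27.6 ± 1.83 FPKM. AT2G19365 rose by 4.26 to 18.2 ± 0.882 FPKM and AT1G36085 by 2.93 to 6.71 ± 1.26 FPKM, both from 0 FPKM in every control library. QQS rose by 2.65 from 4.46 ± 1.78 to 33.4 ± 10.3 FPKM, GSTF14 by 2.28 from 3.32 ± 1.08 to 20 ± 5.76 FPKM and AT2G39980 by 1.82 to 5.96 ± 0.883 FPKM, and these 7 genes had adjusted p at most 0.00034. AT2G05510, a glycine-rich protein gene, fell by 1.15 from 714 ± 138 to 322 ± 74.3 FPKM and sks16 (AT2G23630), of a family of wall-associated oxidase-like proteins, by 1.07 from 18.7 ± 1.58 to 8.58 ± 2.15 FPKM. AT5G24070 fell by 1.11 to 2.90 ± 0.783 FPKM and AT1G07175 by 0.95 to 2.86 ± 0.0929 FPKM. In a fit of the 2 groups alone the calls of AT2G05510 (adjusted p = 0.087), sks16 (adjusted p = 0.07) and AT5G24070 (adjusted p = 0.07) ended.

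Other calls rested on single libraries. AT2G28780 rose by 0.99 to 48.1 ± 7.51 FPKM (adjusted p = 0.012), and its call ended without J0951/Col replicate 2 (adjusted p = 0.064) or 3 (adjusted p = 0.082) or Q0990/UAS-YUC4 replicate 3 (adjusted p = 0.097). AT5G55110 fell by 1.27 to 8.35 ± 3.43 FPKM (adjusted p = 0.019), and its call ended without J0951/Col replicate 1 (adjusted p = 0.066) or 3 (adjusted p = 0.11) or Q0990/UAS-YUC4 replicate 3 (adjusted p = 0.12). The call of sks15 (AT4G37160), which fell by 1.05 to 15 ± 4.04 FPKM (adjusted p = 0.0065), ended without J0951/Col replicate 3 (adjusted p = 0.053). AT5G10130 fell by 0.98 to 32.3 ± 8.86 FPKM (adjusted p = 0.018), and its call ended without J0951/Col replicate 1 (adjusted p = 0.082), 2 (adjusted p = 0.053) or 3 (adjusted p = 0.068) or Q0990/UAS-YUC4 replicate 3 (adjusted p = 0.087). XPL1 (AT3G18000), a methyltransferase of phospholipid synthesis, fell by 0.95 to 63.5 ± 22.9 FPKM (adjusted p = 0.027), and its call ended without J0951/Col replicate 2 (adjusted p = 0.10) or 3 (adjusted p = 0.11) or Q0990/UAS-YUC4 replicate 2 (adjusted p = 0.055) or 3 (adjusted p = 0.19). In a fit of the 2 groups alone these 5 genes had adjusted p of 0.12, 0.11, 0.097, 0.11 and 0.14.

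Among the lists, camera called auxin transport lower (adjusted p = 0.0055, and adjusted p = 0.40 with an estimated correlation). PIN2 (AT5G57090), an auxin efflux carrier of the root tip, fell by 0.46 from 59.9 ± 3.23 to 43.4 ± 6.04 FPKM (adjusted p = 0.026), and 5 genes fell adjusted over the list alone. The call of PIN2 ended without J0951/Col replicate 1 (adjusted p = 0.058), 2 (adjusted p = 0.096) or 3 (adjusted p = 0.10) or Q0990/UAS-YUC4 replicate 3 (adjusted p = 0.13), and in a fit of the 2 groups alone (adjusted p = 0.14). The cell cycle list was called lower (adjusted p = 0.00092, and adjusted p = 0.45 with an estimated correlation), as were abscisic acid and water stress (adjusted p = 0.0031, and adjusted p = 0.40 with an estimated correlation) and root meristem (adjusted p = 0.0092, and adjusted p = 0.63 with an estimated correlation). Salicylate and defence (adjusted p = 0.0092, and adjusted p = 0.40 with an estimated correlation) and photosynthesis (adjusted p = 0.019, and adjusted p = 0.71 with an estimated correlation) were called higher. In these 5 lists limma called 0 genes, and 5 cell cycle, 4 abscisic acid, 6 root meristem, 5 salicylate and 3 photosynthesis genes had an unadjusted value under the threshold in the direction of the list. Adjusted over the list alone, the counts were 1, 4, 2, 5 and 0.

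The comparison called 88 genes, 36 higher and 52 lower, of which 13 changed at least 2-fold, while 3866 had an unadjusted value under the threshold. The share called higher was 40.9%, with 23.7% under median-of-ratios scaling and 81.2% in a fit of the 2 groups alone, where 16 genes were called. The count was 142 with a minimum of 5 FPKM, 198 with median-of-ratios scaling and 717 with library weights. It was 44, 34 and 22 without J0951/Col replicates 1, 2 and 3, and 264, 250 and 20 without Q0990/UAS-YUC4 replicates 1, 2 and 3. Camera called 6 of 28 lists and with an estimated correlation 0, with 2 at an unadjusted p under 0.05, and the 22 lists not called had adjusted p between 0.053 and 0.92.

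**Figure D3:**
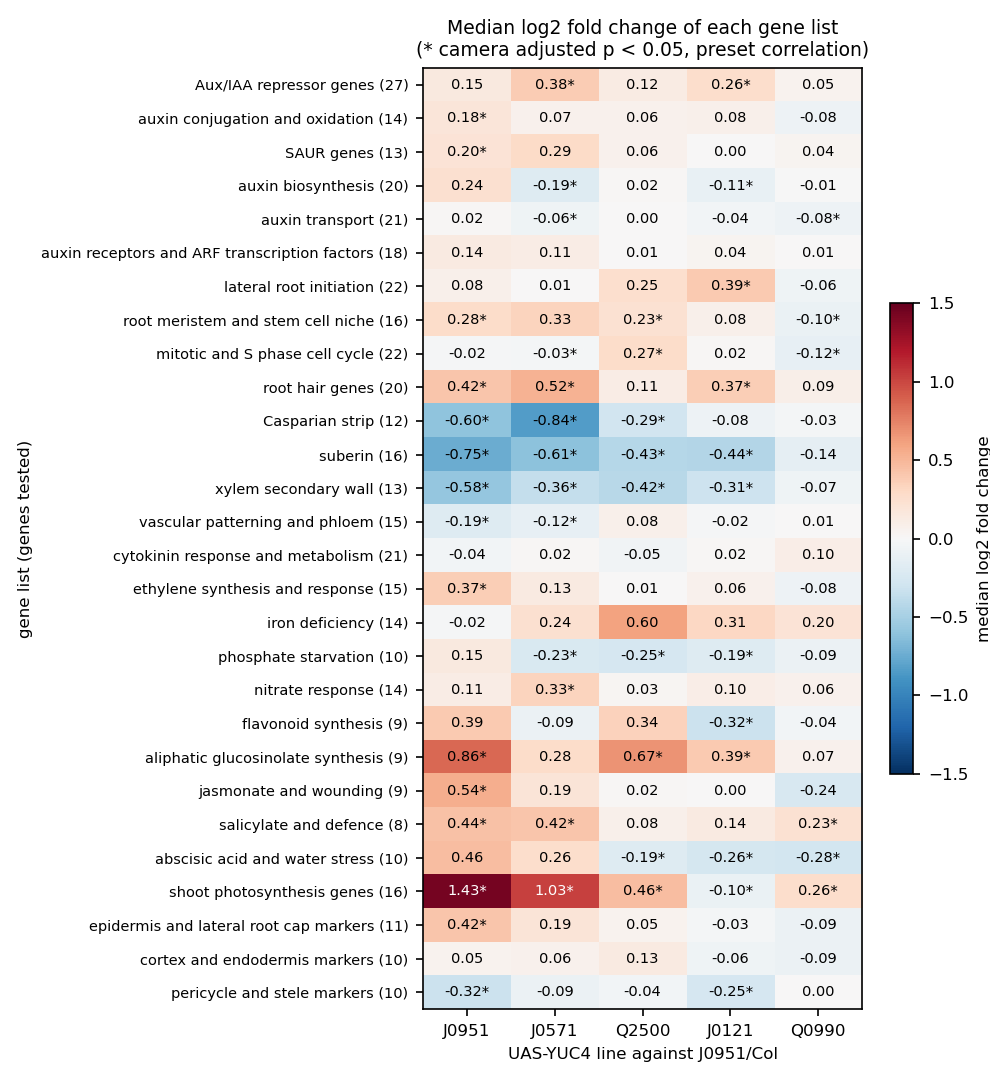
Median log2 fold change against J0951/Col of the 28 gene lists (vertical axis) in the 5 UAS-YUC4 lines (horizontal axis), with a star where the camera adjusted p at the preset correlation was under 0.05. Suberin stood at -0.75 in J0951/UAS-YUC4 and -0.14 in Q0990/UAS-YUC4, and photosynthesis at 1.43 and 0.26.

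Across lines, 4 lists were called in no comparison by camera at the preset correlation. In J0951/UAS-YUC4 the auxin receptor and ARF list had 6 of 18 genes higher (adjusted p = 0.10), the cytokinin list had 7 of 21 higher and 6 lower (adjusted p = 0.83) and the iron deficiency list had 2 of 14 higher and 2 lower (adjusted p = 0.74). In J0571/UAS-YUC4 the cortex and endodermis list had 2 of 10 higher and 4 lower (adjusted p = 0.05). In Q0990/UAS-YUC4 the cytokinin list had an adjusted p of 0.062, and it was called higher with median-of-ratios scaling (adjusted p = 0.046). Among cytokinin genes, ARR15 (AT1G74890), a response regulator, rose by 1.64 in J0951/UAS-YUC4, and ARR7 (AT1G19050) fell by 1.46 on the log2 scale, and both were picked out after their values were seen. In some lists the direction of the test differed in sign from the median or the mean, or 1 of these rounded to 0. There were 6, 5, 9, 6 and 4 such lists in the J0951, J0571, Q2500, J0121 and Q0990 comparisons. None of them was called.

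The question of which genes changed the same way in all 5 lines was answered by 9 genes, 6 higher and 3 lower. QQS rose by a mean of 2.97, from 4.46 ± 1.78 FPKM in the control to between 33.4 ± 10.3 and 46.8 ± 0.590 FPKM. GSTF14 rose by a mean of 2.22, AT2G39980 by 1.76, AT2G28780 by 1.07, AT1G18330 by 0.75 and AT3G54040 by 0.58. PME2 (AT1G53830), a pectin methylesterase, fell by a mean of 0.95, CHX17 (AT4G23700), a cation exchanger, by 0.85 and AT1G16022 by 0.69. In Q0990/UAS-YUC4, where YUC4 was not called, QQS rose by 2.65, against 2.92 to 3.18 in the other lines. GSTF14 rose there by 2.28 against 2 to 2.49, while PME2 fell by 0.41 against 0.77 to 1.75. These 9 genes therefore cannot be assigned to YUC4. A difference particular to J0951/Col could give such changes, and it would enter the J0951 comparison too. If the lines were independent 0.01 genes would be higher in all 5 and 0.0013 lower. In 20 simulations that kept the shared control libraries but changed no group the mean count was 0. With no group changed almost no gene can be called in any line. That 0 therefore does not measure what the shared control libraries add to lines that do change. The lines share their 3 control libraries, so part of the excess over independence may come from these libraries. The count was 5 and 2 without J0951/Col replicates 2 and 3, 26 and 34 without Q2500/UAS-YUC4 replicates 1 and 3, and 15, 27 and 4 without Q0990/UAS-YUC4 replicates 1, 2 and 3. It was 5 without the filter, 15 with a minimum of 5 FPKM, 16 with median-of-ratios scaling (4 higher and 12 lower), 14 with quantile normalization (6 and 8), 17 with a replicate block (8 and 9) and 19 with library weights (12 and 7). Of the 9 genes, only QQS and GSTF14 kept every call in every line when any 1 library was left out.

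Each of the other 7 genes lost a call in some line when 1 library was left out. In the Q0990 comparison AT1G18330 had adjusted p of 0.07, 0.11 and 0.13 without J0951/Col replicates 2 and 3 and Q0990/UAS-YUC4 replicate 3, and AT3G54040 had 0.068 and 0.11 without J0951/Col replicate 3 and Q0990/UAS-YUC4 replicate 3. The call of PME2 ended there without any J0951/Col replicate or Q0990/UAS-YUC4 replicate 1 or 3, at adjusted p from 0.059 to 0.13. That of CHX17 ended without any J0951/Col replicate or Q0990/UAS-YUC4 replicate 2 or 3, at 0.068 to 0.12, and that of AT1G16022 without any J0951/Col replicate or Q0990/UAS-YUC4 replicate 3, at 0.11 to 0.24. In the J0121 comparison AT1G18330 lost its call without any J0951/Col replicate or J0121/UAS-YUC4 replicate 2 or 3, at 0.051 to 0.12, and CHX17 without J0951/Col replicate 1 or 3 or J0121/UAS-YUC4 replicate 2 or 3, at 0.052 to 0.07. In the Q2500 comparison AT2G39980 lost its call without J0951/Col replicate 3 (adjusted p = 0.054) or Q2500/UAS-YUC4 replicate 1 (adjusted p = 0.066), and AT3G54040 without J0951/Col replicate 3 or Q2500/UAS-YUC4 replicate 1 or 2, at 0.081 to 0.16. AT3G54040 also lost it in the J0951 comparison without J0951/Col replicate 3 (adjusted p = 0.20) or J0951/UAS-YUC4 replicate 1 (adjusted p = 0.078) or 3 (adjusted p = 0.076), and CHX17 in the J0571 comparison without J0571/UAS-YUC4 replicate 2 (adjusted p = 0.054).

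The 5 UAS-YUC4 lines also differed from each other, and the F test called 11957 of 19260 genes (62.1%). J0951/UAS-YUC4 was set apart from the mean of the other 4 lines by 9784 genes, 4643 higher and 5141 lower. AT5G04120 was higher there by 4.54, at 113 ± 15.5 FPKM against 5.19 ± 4.47 FPKM (SD, n = 12), AT3G28320 by 3.69, ASN1 by 3.58 and ICS2 (AT1G18870), an isochorismate synthase, by 3.29 at 40.4 ± 10.2 FPKM. The plastid ribosomal protein genes ATCG00780, ATCG00800 and ATCG00810 were lower by 3.15, 3.11 and 2.90 and AT3G05900 by 2.89, and the adjusted p was at most 5.4e-06 for these 8 genes.

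J0571/UAS-YUC4 was set apart by 3092 genes, 2073 higher and 1019 lower. The share higher was 67%, and 44% with median-of-ratios scaling. AT1G64795 was higher by 5.94, at 63.8 ± 11.4 FPKM against 0.0467 ± 0.109 FPKM (SD, n = 12), AT4G08380 by 2.53, XTH26 by 1.87 and AT5G02760, a protein phosphatase gene, by 1.55. AT5G46890 and AT5G46900 were lower by 2.86 and 2.45, AT5G04120 by 2.77 and AT4G16215 by 2.11, with adjusted p at most 0.00021. AT4G16215 does not mark this line, where it stood at 0.453 ± 0.185 FPKM, with 0.333 ± 0.218 in the control and 85.2 in Q0990/UAS-YUC4. The count was 1658, 1921 and 1735 without J0571/UAS-YUC4 replicates 1, 2 and 3, and 4772 with library weights.

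Q2500/UAS-YUC4 was set apart by 1459 genes, 754 higher and 705 lower. AT5G63250 was higher by 1.94, GRP5 (AT3G20470), a glycine-rich protein gene, by 1.85 at 119 ± 38.0 FPKM, AT4G29020 by 1.74 and PDF1 (AT2G42840), an epidermal gene, by 1.72 at 89.3 ± 30.5 FPKM. HIS1-3 was lower by 1.34, AT2G39980 by 1.22, AT5G51470 by 0.86 and AT1G23160 by 0.85, with adjusted p at most 0.00065, and that of HIS1-3 was 0.081 with library weights. The count was 377, 416 and 4002 without Q2500/UAS-YUC4 replicates 1, 2 and 3, and 115 with library weights. The share higher was 51.7%, with 73.9% under library weights and 40.8% without the Q0990/UAS-YUC4 group.

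J0121/UAS-YUC4 was set apart by 3123 genes, 1638 higher and 1485 lower. YUC4 was higher by 4.69, AT1G12010, of the family of the enzymes that complete ethylene synthesis, by 1.49 at 59.5 ± 10.4 FPKM, AT2G16586 by 1.49 and AT1G80165 by 1.46. AT4G33550 was lower by 2.17, AT2G41480, a peroxidase gene, by 1.79, AT5G46730 by 1.61 and LHCB1.3 (AT1G29930), a light-harvesting gene, by 1.60 at 36.9 ± 10.5 against 120 ± 50.8 FPKM (SD, n = 12), with adjusted p at most 0.00064. LHCB1.3 was at 58.2 FPKM in the control. The count was 1282, 1355 and 990 without J0121/UAS-YUC4 replicates 1, 2 and 3, 4834 without Q2500/UAS-YUC4 replicate 3, 5146 with library weights and 6404 without the Q0990/UAS-YUC4 group.

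Q0990/UAS-YUC4 was set apart by 6766 genes, 2424 higher and 4342 lower. The share higher was 35.8%, and 49.5% with median-of-ratios scaling. AT4G16215 was higher by 5.24, AT1G23915 by 4.44, AT2G19365 by 4.07 and AT1G36085 by 2.71. YUC4 was lower by 5.13, SAUR76 by 1.83 at 2.02 ± 0.892 FPKM, GH3.3 by 1.81 at 2.48 ± 0.519 FPKM and EARLI1 by 1.73, and the adjusted p was at most 0.00073 for these 8 genes. The count was 3236 without Q0990 replicate 3. Against J0951/Col (SAUR76 1.65, GH3.3 2.71 FPKM) 88 genes were called, so most of the 6766 need not mark this line.

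For pairs of lines, the number of shared called genes was largest between J0951/UAS-YUC4 and J0571/UAS-YUC4, the lines with the most calls, where 1744 were higher in both and 898 lower in both, against 907 and 245 for independent lines. Their log2 fold changes had a covariance of 0.074 over tested genes, against 0.0077 in simulations where the lines had no change of their own and shared only the control libraries. Between J0571/UAS-YUC4 and J0121/UAS-YUC4 973 genes were higher in both and 496 lower in both, against 331 and 67.2, with a covariance of 0.0525 against 0.0076. Between J0951/UAS-YUC4 and J0121/UAS-YUC4 the numbers were 513 and 391, against 400 and 146. Their covariance was 0.0181 against 0.0077. With Q0990 the covariance was -0.0077 for J0951, 0.0249 for J0571, 0.0094 for Q2500 and 0.0329 for J0121, against 0.0076 to 0.0077. J0951 and Q0990 had 18 genes higher in both, 9 lower and 19 opposite. J0121 and Q0990 had 26, 42 and 0. LBD29 was lower in J0951/UAS-YUC4 than in J0121/UAS-YUC4 by 1.65 (adjusted p of the difference = 1.7e-07).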

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

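Of the tests in this part, those of YUC4 in Q0990/UAS-YUC4 and of the photosynthesis genes were chosen after the results were seen, and the test of neighbouring genes before.

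Some genes were called in opposite directions in 2 lines, which is what set them apart for a closer look. There were 229 such genes between J0951/UAS-YUC4 and J0571/UAS-YUC4, 59 between J0951 and Q2500, 303 between J0951 and J0121, and 19 between J0951 and Q0990. Between J0571 and Q2500 there were 24, between J0571 and J0121 54, between J0571 and Q0990 15, and between Q2500 and J0121 1. In each of these pairs more genes were called in the same direction. Between J0951 and J0571, 1744 were higher in both and 898 lower in both. The number of opposite calls expected for independent lines was not computed, so these counts do not show an excess. AT5G04120 rose by 2.38 in J0951/UAS-YUC4 and fell by 3.46 on the log2 scale in J0571/UAS-YUC4 (difference 5.85, adjusted p = 1.2e-09). ICS2 rose by 2.20 and fell by 1.54 in the same lines (difference 3.74, adjusted p = 4.3e-05), and VSP1 rose by 1.28 and fell by 1.72 (difference 3, adjusted p = 0.00014). LBD29 fell by 0.37 in J0951/UAS-YUC4 and rose by 1.28 in J0121/UAS-YUC4, and AT2G41480 rose by 2.02 and fell by 1.11 (difference 3.13, adjusted p = 2.4e-08).

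For the genes called in opposite directions, different sites of YUC4 expression could be at work, and so could inherited differences between the driver lines. Of the 300 top genes, 20% had a top neighbour of the same direction within 3 genes in the J0571 comparison and 14.4% in the J0951 comparison, a ratio of 1.39, with 11.7%, 10.3% and 11% in the Q2500, J0121 and Q0990 comparisons and 4.5% for random genes. This leaves inherited differences open, because the top genes are only a part of the called genes and an accession background need not place changed genes side by side. A driver line with its own Col control would show which differences come with the driver line. It would not part the site of YUC4 expression from its level, which was 37.6 FPKM in J0951/UAS-YUC4 and 825 FPKM in J0121/UAS-YUC4.

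YUC4 in the libraries labelled Q0990/UAS-YUC4 was near the control level in 1 library and reached 11.95 FPKM in another. An exchange with J0951/Col libraries does not account for it, since no library labelled J0951/Col exceeded 0.3 FPKM. Plants without an active transgene, with YUC4 reads carried over from other libraries, remain possible, because 11.95 FPKM is 1.4% of the J0121/UAS-YUC4 mean. Uneven expression among the plants of a library could give the same values. Genotyping or reads across the UAS-YUC4 junction would tell these apart.

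Photosynthesis genes were higher in J0951/UAS-YUC4 and J0571/UAS-YUC4. Shoot tissue of one kind in different shares would give every gene the same ratio of rises, and over 14 genes the library ranges gave an upper bound of 0.56 at RBCS2B and a lower bound of 0.83 at PSAF. The upper bounds of LHCB2.1 (0.66) and RBCS3B (0.79) also lay under 0.83, but these 3 genes stood between 0.0733 and 0.423 FPKM in the control and have close copies, and over the 10 genes with at least 5 FPKM there the bounds of 0.83 at PSAF and 1.17 at LHCA1 left room for a single ratio. That limit, set after the values were seen, leaves out the 4 genes with the lowest ratios (0.21 to 0.26), which rose by 6.13 to 16.2 FPKM in J0951/UAS-YUC4, so one kind of shoot tissue stays open and is not favoured. Shoot tissue of differing make-up stays open too. The 8 plastid-encoded photosynthesis transcripts tested were too low to decide. They summed to 4.45 FPKM in J0951/UAS-YUC4 (libraries 3.99 to 4.78), 3.19 FPKM in J0571/UAS-YUC4 and 2.57 to 4.17 FPKM in the control. Greening of root cells could also raise photosynthesis genes.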

How the results depend on the processing

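All alternatives here were chosen before the results were seen, except the fits without the Q0990 group. Most counts stayed within a factor of 1.5, and the exceptions follow.

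In the Q2500 comparison 400 genes were called with library weights and 679 with only the 2 groups, against 2180. In the J0121 comparison library weights gave 4409 against 2557. In the Q0990 comparison the count of 88 became 142 with a minimum of 5 FPKM, 198 with median-of-ratios scaling, 717 with library weights and 16 with only the 2 groups. Library weights gave 4772 genes for J0571 set apart, 115 for Q2500 and 5146 for J0121, and J0121 had 6404 without the Q0990 group. The F test gave 10500 without that group. The 9 genes common to all 5 lines became 5 without the filter, 15 with a minimum of 5 FPKM, 16 with median-of-ratios scaling, 14 with quantile normalization, 19 with library weights and 17 with a replicate block. A fit without the Q0990 group called 472 genes in the same direction in the 4 other lines, against 425 for those lines with it.

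With 1 library left out, counts ranged from 5716 to 7052 for J0951, 3566 to 4387 for J0571, 880 to 3526 for Q2500, 1170 to 1681 for J0121 and 20 to 264 for Q0990. The F test ranged from 10384 to 12748. Genes setting a line apart ranged from 7277 to 10381 for J0951, 1658 to 3966 for J0571, 377 to 4002 for Q2500, 990 to 4834 for J0121 and 3236 to 7730 for Q0990, and genes common to all 5 lines from 2 to 34.

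Signs turned only in panel genes that were not called. LBD18 in J0951 stood at 0.005 without J0951/Col replicate 1 and at -0.086 without replicate 2. GH3.1 in J0571 stood at -0.023 with quantile normalization and -0.019 without J0571/UAS-YUC4 replicate 2, with 0.171 without replicate 3. RSL4 in Q2500 stood at -0.003 with median-of-ratios scaling, -0.013 with quantile normalization and -0.011 without Q2500/UAS-YUC4 replicate 3, with 0.077 without replicate 1. In Q0990, IAA19 stood at -0.01 with median-of-ratios scaling, -0.022 with quantile normalization, -0.095 without J0951/Col replicate 3, 0.11 without J0951/Col replicate 1 and -0.001 without Q0990/UAS-YUC4 replicate 1, and IAA5 at -0.1 without J0951/Col replicate 3 and 0.16 without replicate 2. Without Q0990/UAS-YUC4 replicate 2, GH3.3 stood at 0.024, LBD16 at 0, LBD29 at 0.032 and RSL4 at -0.056. Without replicate 3 of that group GH3.5 stood at 0.047 and LBD16 at 0.002, and without J0951/Col replicate 2 LBD29 stood at 0. At the other end, without Q0990/UAS-YUC4 replicate 1, GH3.5 stood at -0.165, LBD16 at -0.17 and RSL4 at 0.212, without its replicate 3 GH3.3 stood at -0.191, and without J0951/Col replicate 3 LBD29 stood at -0.173. YUC4 in Q0990 had an adjusted p of 0.036 with library weights.

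With an estimated correlation camera called 0 lists in J0951, J0571, Q2500 and Q0990 and 2 in J0121. The fry test called 22, 20, 8, 7 and 0 lists in the order J0951, J0571, Q2500, J0121 and Q0990. Directions turned only in lists that camera did not call, with these adjusted p. Under fry they were auxin transport 0.627, cell cycle 0.99 and cytokinin 0.12 in J0951, and cytokinin 0.27 and iron deficiency 0.642 in J0571. In Q2500 they were auxin receptors and ARF 0.719, root hair 0.775, cytokinin 0.506, nitrate 0.739 and cortex and endodermis 0.774. In J0121 they were cell cycle 0.661, cytokinin 0.671 and cortex and endodermis 0.486, and in Q0990 SAUR 0.835 and Casparian strip 0.898. Under median-of-ratios scaling they were cytokinin 0.937 in J0951, iron deficiency 0.946 in J0571, root hair 0.92 in Q2500, auxin receptors and ARF 0.933 in J0121, and SAUR 0.946 and auxin receptors and ARF 0.946 in Q0990. A pseudocount of 0.1 turned SAUR in Q0990 (0.939) and a replicate block turned auxin conjugation in J0571 (0.911), a list that fry called higher (adjusted p = 0.0024).

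Some lists gained or lost a call with other settings. Median-of-ratios scaling called abscisic acid in J0951 (0.0256), root meristem in J0571 (0.0365), lateral root initiation in Q2500 (0.0308) and cytokinin in Q0990 (0.0463). A pseudocount of 0.1 called cortex and endodermis in J0571 (0.0499) and epidermis in Q0990 (0.0484) and ended the call of SAUR in J0951 (0.0704), and a replicate block called abscisic acid in J0951 (0.0489).

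Replicate numbers did not pair libraries across groups, since correlations of deviations within a number ran from -0.27 to 0.38 over 15 pairs for each of 3 numbers and 8 of 18 libraries were closest to one of the same number. Genes called with the replicate block were 7813, 5321, 2264, 2498 and 127 in the same order of lines. With median-of-ratios scaling, genes still called and in the same direction were 6704 of 7796 in J0951, 1620 of 2180 in Q2500, 1722 of 2557 in J0121 and 88 of 88 in Q0990, and the cause was not tested. FPKM values without read counts limit what can be said of genes at low levels. The control shares its driver with J0951/UAS-YUC4 only, so the other 4 comparisons cannot part the driver from YUC4.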

Other observations

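A few genes were nearly private to 1 line, by a rule set after their values were seen. In J0951/UAS-YUC4 they were AT3G28320 at 20.83, 24.31 and 20.55 FPKM, with at most 2.11 FPKM in any other library, its neighbours AT3G28310, AT3G28290 and AT3G28300, and RNS1 (AT2G02990), TPPJ (AT5G65140), OCT1 (AT1G73220) and AT5G38910. AT3G28290 and AT3G28300 are near-identical copies and carry the same values, so they cannot be told apart. J0571/UAS-YUC4 had AT1G64795 at 51.2, 73.29 and 66.93 FPKM, with at most 0.28 FPKM elsewhere, and AT4G08380. Q0990/UAS-YUC4 had AT4G16215, AT1G23915, AT1G36085 and AT2G19365, the last at 18.46, 18.9 and 17.2 FPKM against at most 1.24 FPKM elsewhere.

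The 4 lines other than Q0990 shared 425 genes called in the same direction, 206 higher and 219 lower, against 5.4 and 0.5 for independent lines. The mean was 0 in simulations in which no group changed. Almost no gene can be called in these, so that 0 does not measure what the shared control libraries add.

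Of the next tests, the ratio over the 4 lines was chosen after the results were seen, and the splits and regroupings before. A difference between J0951/Col and all other plants that does not come from YUC4 could produce such a shared set. It would then appear at full size in Q0990/UAS-YUC4, where YUC4 was low, but the median ratio of the Q0990 change to the mean of the 4 lines was 0.32, with quartiles of 0.16 and 0.5. Of the 425 genes, 379 changed in Q0990/UAS-YUC4 in the direction of the 4 lines, and 25 (5.9%) had a ratio of at least 0.75. The genes were selected by their calls in the 4 lines, which can enlarge the change there and lower the ratio. With no change in Q0990 the simulated ratio was 0.1 and at most 0.11, so a part of the shared change may lie in the control libraries.

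The 6 libraries of each comparison with J0951/Col can be split in 10 ways, which is too few for a share under 0.05. In each comparison 1 split, the real one, called as many genes. The real and the highest other count were 7796 and 0 for J0951, 5275 and 0 for J0571, 2180 and 43 for Q2500, 2557 and 0 for J0121 and 88 and 1 for Q0990.

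In 100 regroupings of the libraries, the real one included, 1 called as many genes in the F test (11957 real, 3120 highest other). For J0951 set apart it was 1 (9784 and 116), for Q2500 1 (1459 and 116), for Q0990 1 (6766 and 2), and for the genes common to all 5 lines 1 (9 and 0). For J0571 set apart it was 3 (3092 and 6873) and for J0121 4 (3123 and 7279). The larger counts there had 2 or 3 J0951/UAS-YUC4 libraries together. Mixed lines widen the spread within groups, so these counts do not test 1 line.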
